A study of Homo sapiens with 38 samples.

How the data were processed

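Saliva of 38 participants was studied. Per the labels' protocols, 5 ml of unstimulated whole saliva were collected after at least 1 hour without food, drink or oral hygiene, and total RNA was taken from the stored supernatant with a column kit. The labelled RNA was hybridised to Affymetrix whole-genome expression arrays of 54675 probe sets. The labels gave the IR group of each array and its glycaemic state, and each array was taken as 1 participant. P-values therefore measure the spread between participants, and the number of arrays limits the precision.

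The deposited values were linear signal intensities, 1 per probe set and array. They were made with MAS5, per the submitters' processing notes, with the version not given in the sources used here. The scaling target of the arrays and any masking of absent probe sets were also not given there. Array medians lay between 11.1 and 13.2, and 2.56% to 3.31% of the values of an array stood at exactly 1. No detection calls were used here, and background could only be judged from the signals themselves.

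Intensities were transformed as log2(signal + 16) with no further normalisation, since the array medians differed by less than 1 on the log2 scale. A log2 difference on this scale understates the change of dim genes. The platform annotation gave 41091 probe sets 1 gene symbol and 1801 several, and 11721 probe sets were unnamed here, beside 62 control probe sets that were left out. The gene identifier of 41037 of the 41091 matched the reference table, and 0 symbols needed updating. Probe sets with several symbols were named by none. Each of 19775 genes was represented by its probe set of highest mean, and genes whose mean lay in the upper 50% of the named probe sets were tested, at a mean log2 of at least 4.86 (a signal of 13.1). This left 13210 genes. No genome build was used, and no coordinates are given.

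Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with an intensity trend), with Benjamini-Hochberg adjustment and a threshold of 0.05. IR high was compared with IR low over all 38 arrays, and pre-diabetes with healthy with IR group as an additive term. A fit with 4 group means gave IR high against IR low within healthy and within pre-diabetes participants, pre-diabetes against healthy within IR high, and the interaction. All arrays shared 1 estimate of the spread there, because pre-diabetes IR low held only 4. Where these 4 arrays varied more than the others, the standard errors and p-values understate their spread. Standard errors are those of the moderated fit. Their median was 0.12 over all genes and 0.40 over the abundant genes for IR in all participants, and 0.20 and 0.65 for IR within pre-diabetes.

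The 20 gene lists held markers of neutrophils, monocytes and macrophages, T and NK cells, B and plasma cells, erythroid cells, oral squamous epithelium and salivary glands, liver markers as a background check, insulin signalling, NF-kB and cytokines, type I interferon, adipokines and receptors, glycolysis, fatty acid and cholesterol metabolism, oxidative phosphorylation, cytosolic ribosomal proteins, endoplasmic reticulum stress, immediate early and heat shock genes, antimicrobial proteins, and a list of 6 genes recalled from the study's literature. The recalled list may have been chosen on these samples, and CAP1 of it was not measured by a probe set with 1 symbol. Lists with at least 5 tested members were tested with limma's camera at a preset correlation of 0.01, with camera at an estimated correlation and fry beside it. Camera compares a list with the other genes. Fry's directional test asks whether its genes move on balance to 1 side.

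A list score per array, the mean deviation of its genes from their 38-array means, was compared by two-sided permutation tests with 100000 resamples, or by exact enumeration where a group held fewer than 10 arrays. Quality measures were the log2 ratios of 3' to 5' control probe sets of ACTB and GAPDH, the median value and the median Spearman correlation with the other arrays. The leave-one-out score picked 10 genes by limma within each fold and scored the left-out array by diagonal discriminant analysis, with 100 permutations of the labels.

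The genes named in the text followed a rule. For IR in all participants these were the 10 genes of lowest p in each direction, for each list up to 4 tested members of lowest p, for the recalled list all measured members, and for each other comparison the 5 genes of lowest p in each direction. Not every gene the rule allows is named. Genes named only by the level of a list or of an array, and genes called only under an alternative, were chosen after their values were seen. Genes of the Y chromosome and XIST were left out of naming. The groups, designs, lists, naming rule and alternatives were fixed before the data were examined, except for alternatives said to be chosen after seeing the data.

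The fits were tested on simulated data with 13210 genes, of which 50 were changed at each of 4 sizes. For IR in all participants, changes of 0.5, 1, 2 and 3 on the log2 scale were recovered in 48%, 94%, 100% and 100% of genes, with 8 false among 179 calls. For IR within pre-diabetes the shares were 10%, 84%, 98% and 96%, with 9 false among 153 calls. For the interaction they were 2%, 56%, 90% and 96%. The simulated noise was independent between genes and of equal spread in every group, and the changed genes were drawn from all tested genes. In the real data genes of a list were correlated, and abundant genes had larger standard errors. The shares may therefore not hold for abundant genes or for pre-diabetes IR low, and false calls may be more frequent.

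The alternatives were offsets of 1 and 64, no filter and a filter at the upper 25%, quantile normalisation, the mean of a gene's probe sets and each probe set by itself, leaving out probe sets open to cross-hybridisation, array weights, eBayes without trend or with robust moderation, and the GAPDH ratio as a covariate. Other covariates, only the compared groups in the fit, the Wilcoxon test, the replicate number as a block, and each participant left out in turn were also tried. Added after seeing the data were tests of the abundant genes alone and tests without the 3 arrays with an ACTB 3' signal under 500. No scan date or batch was given in the sources used here, so batches were not tested. The highest Pearson correlation between 2 arrays was 0.831, so no pair looked like 1 library deposited again.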

Results

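Gene expression was measured in saliva supernatant of 38 participants, with 1 array each. The study's title names salivary transcripts as markers of insulin resistance (IR), and participants were divided at a HOMA-IR of 2.5, an index of insulin resistance computed from fasting glucose and fasting insulin. This gave 15 arrays of low and 23 of high IR risk, called IR low and IR high here. The labels also gave a glycaemic state, healthy in 19 participants and pre-diabetes in 19. The 4 groups held 11 healthy IR-low, 8 healthy IR-high, 4 pre-diabetes IR-low and 15 pre-diabetes IR-high arrays.

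Only a small part of each array gave a signal over 100. The median signal of an array lay between 11.1 and 13.2, and 484 to 1850 of 54675 probe sets (median 939) had a signal over 100. The 3' control probe set of ACTB, the gene of cytoplasmic beta-actin, ranged from 38.3 to 4876 with a median of 2976. On 3 arrays it was under 500, at 38.3 and 313 on pre-diabetes IR-low replicates 4 and 3 and at 249 on pre-diabetes IR-high replicate 1. The array with ACTB at 38.3 still held 484 probe sets over 100, so such signals need not all come from human mRNA. Of 13210 genes tested, 505 had a mean signal of at least 100 and are called abundant here.

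**Figure D1:**
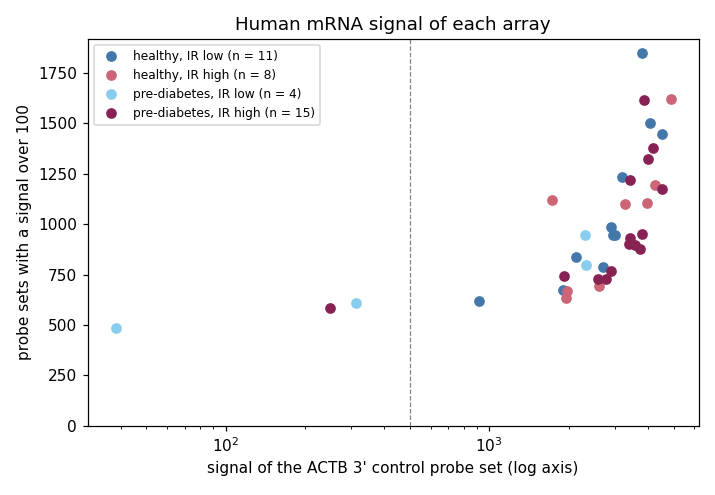
Signal of the 3' control probe set of ACTB (log axis) against the number of probe sets with a signal over 100, 1 point per array, coloured by group. The dashed line marks an ACTB signal of 500, and the 3 arrays left of it held 484, 586 and 610 probe sets with a signal over 100.

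The abundant transcripts included markers of several cell types of the mouth. Of 33 neutrophil markers tested, 21 were abundant, and S100A8, a subunit of calprotectin, had a median signal of 3131 over the arrays. The oral squamous epithelium list had 14 abundant members of 37, led by the cornified envelope gene SPRR3 at 3245, and the salivary gland list had 12 of 27, led by the mucin gene MUC7 at 2763. All 53 cytosolic ribosomal protein genes tested were abundant (RPL41 at 2270), as were 6 of 15 monocyte and macrophage markers. None of 14 T and NK cell, 12 B and plasma cell or 6 erythroid markers was abundant, with highest median signals of 31.2 (CD247), 54.2 (BANK1) and 28.2 (HBB). Liver markers served as a background check, and 1 of 15, SERPINA1 at 218, was abundant.

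The study's stated grouping, IR high against IR low in all participants, asked which transcripts accompany insulin resistance. Pre-diabetes was present in 15 of 23 IR-high and 4 of 15 IR-low participants. This comparison had no term for glycaemic state, so its differences can mix the 2 labels. With glycaemic state as a covariate limma also called 0 genes, with 627 at an unadjusted p under 0.05. The neutrophil gene S100A12 had a mean log2 level of 8.32 ± 1.11 (SD, n = 23) in IR high and 7.12 ± 1.43 (SD, n = 15) in IR low, a difference of 1.20 ± 0.40 (SE), or 2.29-fold in signal + 16. It lay above the IR-low mean on 21 of 23 IR-high arrays and below the IR-high mean on 11 of 15 IR-low arrays. CAMP, which encodes the antimicrobial peptide cathelicidin, differed by 0.50 ± 0.20 (SE) and the chemokine-like PROK2 by 1.19 ± 0.59 (SE). In the other direction PRB3, PRB1 and PRB4, which encode basic proline-rich proteins of parotid saliva, differed by -1.28 ± 0.55, -1.21 ± 0.56 and -1.30 ± 0.60 (SE). The unadjusted p-values of these 6 genes ran from 0.00507 (S100A12) to 0.0491 (PROK2) and their adjusted p was 0.970, so none passed. The PRB genes are near-identical copies, and their probe sets can share transcripts.

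No gene of 13210 passed limma's test at an adjusted p of 0.05, where the lowest adjusted p was 0.840. Unadjusted p-values under 0.05 numbered 603 (295 higher and 308 lower in IR high), or 4.56% of genes, and the Wilcoxon test gave 0 adjusted calls and 571 unadjusted ones. The lowest p-values with higher values in IR high belonged to OAZ3 at 0.32 ± 0.08 (SE, p = 0.000127), MIA at 0.67 ± 0.17 (SE, p = 0.000263), the transcription factor gene YY1 at 0.48 and the gut peptide gene PYY at 0.36. They were followed by MXRA8 (0.60), ZEB2 (0.32), STAU1 (0.54), PPM1F-AS1 (0.30), the T cell co-receptor gene CD8A (0.40) and UNC5CL (0.32). The lowest p-values with lower values belonged to the keratin-associated protein gene KRTAP4-6 at -0.39 ± 0.09 (SE, p = 0.000125), CRHR2 at -0.31, XK at -0.35 and GPLD1 at -0.23. SLC2A13 (-0.32), PLXNA2 (-0.44), NOL9 (-0.33), the tight junction gene CLDN1 (-0.26), SCAF8 (-0.35) and MRPL18 (-0.47) followed. These 20 genes had mean signals of 14.0 to 40.6, near the median of an array, and the adjusted p was 0.840 for OAZ3 and KRTAP4-6 and 0.970 for the others. The PYY value changed sign to -0.06 when probe sets open to cross-hybridisation were left out.

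Of 20 gene lists, 5 passed camera's test against the other genes at its preset correlation, 4 of them higher in IR high. The estimated correlations of these 5 lists were 0.12 to 0.50 against the preset 0.01, so the preset p-values overstate the evidence. The abundant genes as a whole had a median difference of 0.25, with 73.9% of them higher in IR high. Of the 33 neutrophil markers 21 were abundant, and how much of their difference was this general shift was not tested. Neutrophil markers had a positive difference in 30 of 33 members, with a median log2 difference of 0.44 (adjusted p = 1.87e-06). This call was lost at adjusted p = 0.578 with an estimated correlation. The NF-kB and cytokine list was positive in 21 of 27 members with a median of 0.26 (adjusted p = 0.0154), with IL6 at 0.33 ± 0.10 (SE) and SOD2, a mitochondrial superoxide dismutase, at 0.84 ± 0.52 (SE). This list had adjusted p = 0.718 with an estimated correlation. Antimicrobial peptides and proteins were positive in 13 of 17 members with a median of 0.24 (adjusted p = 0.00869), and adjusted p = 0.523 with an estimated correlation. Salivary gland secretory markers were negative in 22 of 27 members with a median of -0.41 (adjusted p = 1.21e-05), and adjusted p = 0.523 with an estimated correlation. The salivary members of lowest p were PRB3, PRB1, PRB4 and SMR3A (-0.44).

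The list recalled from the study's literature (PRKCB, S100A12, IL1R2, CAMP and VPS4B measured here) was positive in 4 of 5 members, with a median of 0.59 and an adjusted p of 0.000115. This became adjusted p = 0.199 with an estimated correlation. PRKCB, a protein kinase C gene, differed by 0.65 ± 0.27 (SE), VPS4B by 0.59 ± 0.23 (SE) and IL1R2, a decoy receptor for interleukin-1, by -0.14 ± 0.35 (SE). Of its genes 4 passed when adjusted over the list alone and 0 over all genes, and since the list may have been chosen on these samples, this is not independent evidence. Among the other lists only CD8A of the T and NK cell list passed when adjusted over the list alone. S100A12 and CAMP stood in the neutrophil, antimicrobial and recalled lists alike, and fry called 0 lists in either direction (lowest adjusted p 0.200).

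The other 15 lists did not pass in camera. Glycolysis (median 0.06, adjusted p = 0.0875), immediate early and heat shock genes (0.28, adjusted p = 0.161) and oral squamous epithelium (0.10, adjusted p = 0.221, with TGM1 at 0.36 and S100A16 at 0.51) had positive medians, as did adipokines and receptors (0.08, adjusted p = 0.340). Cytosolic ribosomal proteins had a median of -0.13 (adjusted p = 0.148) and the type I interferon list one of -0.09 (adjusted p = 0.204). Monocyte and macrophage markers (0.08), T and NK cell markers (-0.02), erythroid markers (0.0054), liver markers (0.0041), insulin signalling (-0.04), fatty acid and cholesterol metabolism (0.03) and endoplasmic reticulum stress (-0.04) all had an adjusted p of 0.647. B and plasma cell markers (-0.02) and oxidative phosphorylation (-0.0095) had an adjusted p of 0.738. Median and mean differed in sign for liver (mean -0.02), insulin signalling (mean 0.02, with a test direction of lower) and oxidative phosphorylation (mean 0.04).

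Each array's list score, its mean deviation over the list's genes, gave the spread between participants. The neutrophil score was 0.17 ± 0.79 (SD, n = 23) in IR high and -0.26 ± 1.07 (SD, n = 15) in IR low, with p = 0.169 in a two-sided permutation test (adjusted p = 0.599 over 20 lists). The salivary gland score was -0.16 ± 0.64 (SD, n = 23) against 0.25 ± 0.82 (SD, n = 15), with p = 0.0961 by permutation (adjusted p = 0.599). The difference between IR groups was thus smaller than the SD within each group for both lists. Compared within glycaemic states, the neutrophil difference was 0.59 (permutation p = 0.0699, adjusted p = 0.309). The salivary gland difference was then -0.26 (permutation p = 0.318, adjusted p = 0.626). Without the 3 arrays of low ACTB signal, a setting chosen after seeing the data, the calls of the NF-kB list (median 0.08, adjusted p = 0.336) and the antimicrobial list (0.16, adjusted p = 0.119) were lost. Cytosolic ribosomal proteins gained one at a median of -0.37 (adjusted p = 6.3e-10, and adjusted p = 0.827 with an estimated correlation). Neutrophil markers (0.23, adjusted p = 0.00101), salivary gland markers (-0.52, adjusted p = 6.3e-10) and the recalled list (0.49, adjusted p = 0.00139) stayed, with adjusted p-values of 0.827, 0.229 and 0.229 with an estimated correlation.

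**Figure D2:**
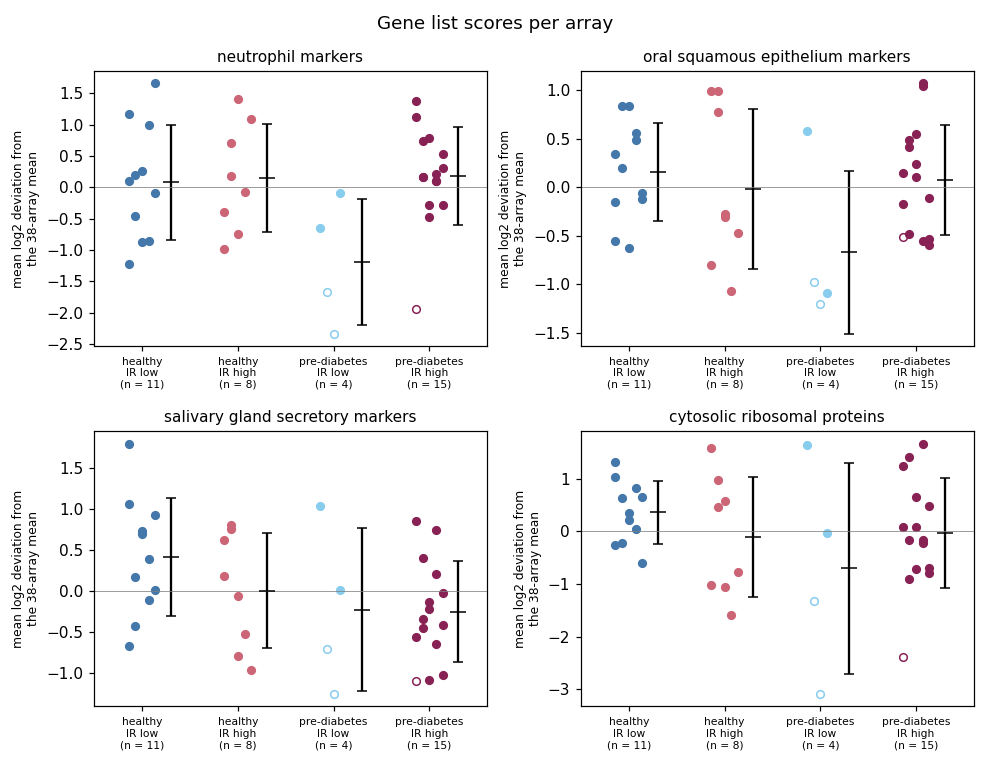
List score of each array (mean log2 deviation of the list's genes from their mean over the 38 arrays) for 4 lists by group, with points for arrays, open circles for the 3 arrays with an ACTB signal under 500, and bars for mean ± SD. The neutrophil mean was -1.19 in pre-diabetes IR low and between 0.08 and 0.18 in the other 3 groups, and the open circles were its lowest points.

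Among healthy participants, 8 IR high were set against 11 IR low. The lowest p-values belonged to TRAPPC1, a subunit of a vesicle tethering complex, at 0.69 ± 0.18 (SE), HDAC2-AS2 at 0.39, PYY at 0.49, PPM1F-AS1 at 0.43 and ZEB2 at 0.43. On the lower side stood the semaphorin receptor gene PLXNA2 at -0.70 ± 0.17 (SE), KRTAP4-6 at -0.49, the scramblase gene XKR8 at -0.88, FOXD4 at -0.48 and TMA16 at -0.32. All had an adjusted p of 1.00. Limma called 0 genes, with 327 (162 higher, 165 lower) at an unadjusted p under 0.05, or 2.48% of genes, and no other test per gene was run on this contrast. The lists were tested here only after the data were seen. The NF-kB and cytokine list was positive in 9 of 27 members with a median of -0.09 (adjusted p = 0.291), the opposite direction to all participants. Camera called ribosomal proteins (-0.50, adjusted p = 7.02e-07) and salivary gland markers (-0.30, adjusted p = 0.000117) as lower in IR high, both with adjusted p = 0.775 with an estimated correlation.

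Among participants with pre-diabetes, 15 IR high were set against 4 IR low, and 3 genes passed limma's test. VDR, the vitamin D receptor gene, rose by 0.96 ± 0.18 (SE) in IR high, from a mean log2 level of 4.70 ± 0.46 (SD, n = 4) to 5.66 ± 0.34 (SD, n = 15) (adjusted p = 0.0359). SLC6A2, which encodes the noradrenaline transporter, rose by 0.98 ± 0.19 (SE) and the antisense RNA gene PHEX-AS1 fell by 1.22 ± 0.24 (SE), both with an adjusted p of 0.0359. All 15 IR-high arrays lay past the IR-low mean for these 3 genes, as did 4 of 4 IR-low arrays short of the IR-high mean for VDR and SLC6A2 and 3 of 4 for PHEX-AS1. The signals were low, at 10.1 and 34.7 for VDR, 13.9 and 43.0 for SLC6A2 and 55.5 and 14.7 for PHEX-AS1 in IR low and IR high. The VDR signal of IR low lay under the median signal of every array, so the size depended on the offset added to the signals, with 1.94 at an offset of 1 and 0.41 at 64. The other 3 probe sets of VDR gave -0.01 to 0.17 and the other 7 of SLC6A2 -0.42 to 0.13, so the probe sets of these genes disagreed.

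CXCL8, the gene of the neutrophil chemokine interleukin-8, differed by 2.21 ± 0.49 (SE), or 4.62-fold in signal + 16, and its other probe set by 2.81. The vasodilator gene ADM differed by 3.06 ± 0.69 (SE), or 8.33-fold in signal + 16, with signals of 84.2 and 819 in IR low and IR high. Both were higher than the IR-low mean on 14 of 15 IR-high arrays, with an adjusted p of 0.0985 over all genes, as for the splicing factor gene SRSF7 (0.97), PCDHB18P (-0.70) and LINC01649 (-1.27, but -0.60 without pre-diabetes IR-low replicate 4). KRTAP4-11 (-0.55) had an adjusted p of 0.125 and ZNF675 (-0.60) one of 0.167. At an unadjusted p under 0.05 stood 1318 genes (706 higher, 612 lower), or 9.98%. The median over the abundant genes was 1.11, with 89.9% of them higher in IR high. In the same groups the ACTB 3' signal was 1245 ± 1240 (SD, n = 4) in IR low and 3219 ± 1059 (SD, n = 15) in IR high.

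The calls of this contrast rested on few arrays. Leaving out pre-diabetes IR-low replicates 1, 3, 4 and 13 in turn gave 9, 2, 0 and 16 limma calls (948 genes at an unadjusted p under 0.05 without replicate 4), and without the 3 arrays of low ACTB signal, a setting chosen after seeing the data, there were 9 calls, of which VDR alone was shared. With only abundant genes tested, also chosen after seeing the data, 85 genes were called, CXCL8 and ADM among them (both adjusted p = 0.0187), and 0 by limma without the 3 arrays (25 at an unadjusted p under 0.05), where CXCL8 differed by 1.07 and ADM by 2.26.

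**Figure D3:**
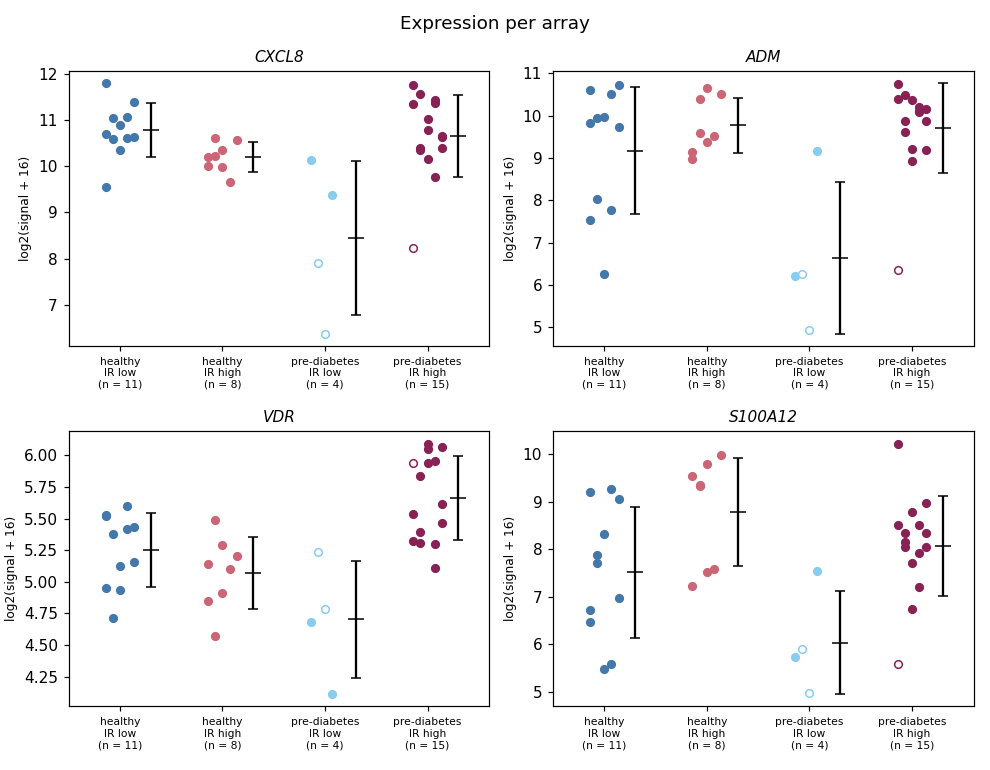
Expression per array of CXCL8, ADM, VDR and S100A12 as log2(signal + 16) by group, with points for arrays, open circles for the 3 arrays with an ACTB signal under 500, and bars for mean ± SD. CXCL8 averaged 8.45 in pre-diabetes IR low and 10.2 to 10.8 in the other 3 groups.

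Pre-diabetes was compared with the healthy state in all participants, adjusted for IR group. Those neutrophil genes with the lowest p-values were lower in pre-diabetes, with S100A12 at -0.99 ± 0.40 (SE), the calprotectin subunits S100A8 and S100A9 at -0.98 ± 0.41 and -0.87 ± 0.41 (SE) and G0S2 at -1.05 ± 0.48 (SE). Among salivary gland genes MUC7 differed by -1.06 ± 0.43 (SE), the cystatin gene CST2 by -1.04 and the statherin gene STATH by -0.91, while TCN1, which encodes a vitamin B12 binding protein, differed by 0.57. All had an adjusted p of 0.957. The lowest p-values belonged to ELAVL4 (0.37), LOC101928937 (0.31), LOC102723847 (0.30), LOC105374809 (0.34) and LOC101926948 (0.52) on the higher side. On the lower side they belonged to WDR88 (-0.88 ± 0.22, SE), PKD2L1 (-0.41), the kinase co-chaperone gene CDC37 (-0.31), KIAA1549 (-0.65) and PIK3R4 (-0.25). Limma called 0 genes, with 624 (373 higher, 251 lower) at an unadjusted p under 0.05, or 4.72%, and no other test per gene was run on this contrast.

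Camera called 7 lists at its preset correlation, all lower in pre-diabetes. The estimated correlations of these 7 lists were 0.09 to 0.78, again above the preset 0.01. The abundant genes as a whole had a median of -0.41 in this contrast, and 11.5% of them were higher in pre-diabetes. Camera set each list against the other tested genes, most of them not abundant. A list with many abundant members can thus be called through this general shift, which was not tested apart. Neutrophil markers were negative in 29 of 33 members with a median of -0.41 (adjusted p = 6.49e-06), and adjusted p = 0.464 with an estimated correlation. Cytosolic ribosomal proteins had a median of -0.38 (adjusted p = 1.02e-05), and adjusted p = 0.561 with an estimated correlation. Salivary gland markers were negative in 24 of 27 members with a median of -0.45 (adjusted p = 0.00019), and adjusted p = 0.464 with an estimated correlation. Oral squamous epithelium had a median of -0.15 (adjusted p = 0.0089), with the protease inhibitor gene CSTB at -0.82 and SPRR1A at -0.77, and adjusted p = 0.561 with an estimated correlation. Antimicrobial peptides and proteins (-0.11, adjusted p = 0.0116), glycolysis (-0.09, adjusted p = 0.0129) and monocyte and macrophage markers (-0.15, adjusted p = 0.0424) each had adjusted p = 0.441 with an estimated correlation. Fry called 0 lists (lowest adjusted p 0.463).

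The 13 lists that did not pass included NF-kB and cytokine genes (-0.08), type I interferon (-0.09) and oxidative phosphorylation (-0.08), each with an adjusted p of 0.0536. Adipokines and receptors (-0.11, adjusted p = 0.0727), immediate early and heat shock genes (-0.23, adjusted p = 0.112), endoplasmic reticulum stress (-0.07, adjusted p = 0.363), fatty acid and cholesterol metabolism (-0.02, adjusted p = 0.485), liver markers (-0.02, adjusted p = 0.521) and insulin signalling (-0.03, adjusted p = 0.654) had negative medians. B and plasma cell (0.09, adjusted p = 0.209), erythroid (0.03, adjusted p = 0.521) and T and NK cell markers (0.03, adjusted p = 0.646) had positive ones. The recalled list had a median of 0.07 and a mean of -0.19 (adjusted p = 0.507), with IL1R2 at -0.41, VPS4B at 0.25, PRKCB at 0.14 and CAMP at 0.07. Without the 3 arrays of low ACTB signal, all of them from participants with pre-diabetes, none of the 7 calls of lower values stayed. The neutrophil median was then -0.0037, S100A9 differed by 0.03, and the ribosomal list was called in the opposite direction at a median of 0.27 (adjusted p = 1.28e-05, and adjusted p = 0.795 with an estimated correlation).

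Within IR high, 15 participants with pre-diabetes were set against 8 healthy ones. The ubiquitin-conjugating enzyme gene UBE2G1 (0.64 ± 0.14, SE), TNFRSF10A-DT (1.08 ± 0.24, SE) and the lipid-binding protein gene OSBPL3 (0.49 ± 0.11, SE) had the lowest p-values, each with an adjusted p of 0.349. VDR was at 0.59 (adjusted p = 0.554) and NDP at 0.40 (adjusted p = 0.600). On the lower side stood NGDN (-0.52, adjusted p = 0.704), CCDC59 (-0.71) and TRAPPC1 (-0.60) with an adjusted p of 0.732, and FASTK (-0.50) and SSNA1 (-0.65) with one of 0.776. Limma called 0 genes, with 646 (415 higher, 231 lower) at an unadjusted p under 0.05, or 4.89%, and no other test per gene was run on this contrast. The median over the abundant genes was 0.03. Camera, run on this contrast after the data were seen, called no list (lowest adjusted p 0.286). Neutrophil markers were positive in 19 of 33 members with a median of 0.05 (adjusted p = 0.872). Of the 7 lists called lower in pre-diabetes over all participants, only salivary gland markers had a negative median within IR high, at -0.24 (adjusted p = 0.450).

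The interaction tested whether the IR difference was larger in pre-diabetes than in the healthy state. CXCL8 had an interaction of 2.79 ± 0.64 (SE) and VDR one of 1.14 ± 0.24 (SE), each with an adjusted p of 0.177. SHISA7 (1.36), CLIP4 (0.71), the somatostatin receptor gene SSTR5 (-1.22) and PCDHB18P (-0.85) shared that value, and the endosomal sorting gene HGS (1.53) had an adjusted p of 0.183. KRTAP4-11 (-0.63) and PHEX-AS1 (-1.18) had an adjusted p of 0.395 and the adhesion gene NECTIN2 (-0.87) one of 0.458. Limma called 0 genes, with 958 (532 higher, 426 lower) at an unadjusted p under 0.05, or 7.25%, and no other test per gene was run on this contrast. The difference of VDR, SLC6A2 and PHEX-AS1 between IR groups was therefore not shown to differ between glycaemic states.

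None of the 4 tested measures of RNA quality passed the test between the IR groups. The log2 ratio of 3' to 5' control probe sets was 0.74 ± 0.71 (SD, n = 23) in IR high and 0.36 ± 1.16 (SD, n = 15) in IR low for GAPDH, with p = 0.214 in a two-sided permutation test (adjusted p = 0.678 over 4 measures). For ACTB it was 1.96 ± 0.59 against 1.69 ± 1.11 (p = 0.339 by permutation, adjusted p = 0.678). The median log2 value was 4.82 ± 0.03 in both groups (p = 0.917 by permutation), and the median correlation of an array with the others was 0.655 ± 0.029 in IR high and 0.649 ± 0.030 in IR low (p = 0.560 by permutation). The median log2 value says little about RNA quality, since it was 4.82 even on the array with an ACTB 3' signal of 38.3. Within pre-diabetes the GAPDH ratio was 0.61 ± 0.79 (SD, n = 15) in IR high and -0.34 ± 0.87 (SD, n = 4) in IR low (exact permutation p = 0.0544, adjusted p = 0.218). The ACTB 3' signal and the number of probe sets over 100 were not tested between groups. Within pre-diabetes their means were 3219 and 988 in IR high against 1245 and 710 in IR low, so comparable RNA quality was not shown.

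Since the study's title speaks of biomarkers, the separation of the IR groups was tested on arrays left out of gene selection. A score of 10 genes gave a leave-one-out area under the curve of 0.545. Of 100 permutations of the IR labels, 43 gave an area as high (p = 0.436), and their median was 0.509. The areas with 5, 20 and 50 genes were 0.667, 0.545 and 0.484, with p-values of 0.149, 0.327 and 0.515.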

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

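The tests without the arrays of low ACTB signal, those of the abundant genes alone and the test of 3 marker lists among the abundant genes were chosen after the results were seen. Single arrays far from the others of their group were sought in 122 sets of 4 to 10 arrays. In 8 of these an array stood apart, where chance gives about 6.1.

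The 4 pre-diabetes IR-low arrays gave 6 of these values. Replicate 1 had an oral epithelium score of 0.576, where the others lay between -1.20 and -0.97, and an erythroid score of 0.184 against -0.06 to -0.02. Replicate 4, an array of low ACTB signal, had log2 levels of 8.41 for LINC01649 against 5.45 to 5.92 and of 4.43 for SRSF7 against 4.26 to 4.27. KRTAP4-11 was at 6.12 on replicate 3, also of low ACTB signal, against 5.42 to 5.47, and ZNF675 was at 5.04 on replicate 13 against 5.71 to 5.76. Among healthy IR-high arrays, SLC2A13 was at 5.46 on replicate 20 against 4.47 to 4.93, and PLXNA2 was at 5.33 on replicate 8 against 4.29 to 4.61.

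The higher neutrophil list in IR high was weighed against little human mRNA on 3 arrays and against RNA degradation. Without the 3 arrays its median log2 difference was 0.23 (95% bootstrap interval -0.26 to 0.70), compared with 0.44 (-0.06 to 0.86) on all arrays, a change of -0.30 to -0.09, so part of the difference rested on these arrays and whether most of it did stays open. These arrays had the lowest neutrophil scores (-2.33, -1.95 and -1.68), and 2 of them were IR low. A smaller difference without them could be foreseen, so the change does not by itself point to little human mRNA as the cause. With the GAPDH 3' to 5' ratio as a covariate the median stayed at 0.44 (-0.06 to 0.98), and the change between the fits had an interval of -0.17 to 0.20. The log2 ratio was -1.23 and -0.85 on pre-diabetes IR-low replicates 4 and 3, where ACTB signal was low. There it may not register RNA loss, so the covariate cannot decide and degradation stays open. Chance could not be excluded either, since 21 of 100 splits gave a neutrophil score difference as large as the real 0.42, the highest other being 0.83. The mean neutrophil score was -1.19 in pre-diabetes IR low and 0.08 to 0.18 in the other groups. Among the healthy it differed by 0.07 between IR groups (exact permutation p = 0.869). A difference in neutrophil RNA with insulin resistance thus stays open, untested by any independent samples.

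Among participants with pre-diabetes, the abundant genes had a median difference of 1.11 (0.79 to 1.49 with the number of arrays of low ACTB signal held fixed) in favour of IR high. Without those arrays it was 0.46 (0.19 to 0.67), a change of -0.94 to -0.44, so these arrays may account for part of it. Since ACTB is itself an abundant gene, a smaller median without them could be foreseen. Only 2 IR-low arrays then remained, so the intervals without those arrays cannot measure the spread between participants. The interval on all arrays leaves out the spread in how many arrays had low ACTB signal. Whether a lower level of all human mRNA alike was the whole cause stays open. The score of abundant neutrophil members minus that of salivary gland members differed by 1.76 between IR groups (exact permutation p = 0.00232, adjusted p = 0.00697 over 3 pairs of lists, the other pairs having 0.0519 and 0.878). This cannot decide, since the scale understates changes of dim genes and a uniform loss can give unequal differences. Over all list members, the IR-high array of low ACTB signal also scored lower for neutrophils (-1.95) than for salivary glands (-1.10). With arrays resampled within groups, 12 salivary gland members had a median of -0.035 (-1.63 to 1.11), 21 neutrophil members 1.94 (0.42 to 3.39) and 14 oral epithelium members 1.69 (-0.32 to 3.10), where IR-low replicates 3 and 4 were low in salivary gland score too (-0.70 and -1.25) and replicate 1 high (1.04). Without the arrays of low ACTB signal these medians were -1.23, 0.73 and 0.72 and the score difference was 2.01 (exact permutation p = 0.025, adjusted p = 0.075, so not passed), and what remained rested on 2 IR-low arrays.

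For the 3 genes called within pre-diabetes, 5 of 100 splits called as many, the highest other 103, so chance could not be excluded. A split with so many calls may reflect a structure of the arrays or correlation between genes, which was not tested. The 5 lists called by camera between IR groups were matched by 39 of 100 splits, the highest other being 12 lists, and chance could not be excluded.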

How the results depend on the processing

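The tests of abundant genes, those without the 3 arrays of low ACTB signal, the permutation test of list scores and the unblocked fit of 30 arrays were chosen after the results were seen. No array stood apart by its correlation with the others, so that planned setting gave no value. The 0 calls for IR in all participants, for IR among the healthy and for pre-diabetes adjusted for IR held under every setting run, including each participant left out for the first (lowest adjusted p 0.840 in limma, 603 genes at an unadjusted p under 0.05, 0 by Wilcoxon). The quality tests stayed at 0 calls, and the areas under the curve ran from 0.332 to 0.667 over all gene numbers and settings (0.399 with 10 genes without the 3 arrays). Of the named genes' values under other settings 1340 kept direction and side of the threshold, 17 lost and 4 gained a call and 6 turned. For list values these numbers were 228, 46, 8 and 18.

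For IR within pre-diabetes the count of 3 became 1 with an offset of 64, 1 (the lower PHEX-AS1) with quantile normalisation, 1 with the GAPDH covariate, 5 without a filter, and 0 with the mean of a gene's probe sets or each probe set by itself (limma, 1020 and 1898 genes at an unadjusted p under 0.05). It became 85 with abundant genes, 9 without the 3 arrays and 0 with both, and ran from 0 to 16 with each IR-low replicate left out. With only pre-diabetes arrays in the fit there were 2 calls, TEX26-AS1 and ZFP69B, and 0 shared. The cause was not tested, beyond the fewer arrays or genes in some settings. Pre-diabetes within IR high gained 1 call without a filter (LINC00174, -0.67, named after its value was seen), and the interaction 1 with abundant genes (CXCL8, adjusted p = 0.0458). The lists called for IR went from 5 to 0 with an estimated correlation, fry or permuted scores and to 8 with glycaemic state as a covariate. Those for pre-diabetes went from 7 to 0 with the first 3 and to 1, in the opposite direction, without the 3 arrays. The causes were not tested.

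For IR, IL1R2 was at 0.48 with the mean of probe sets, 0.023 with the glycaemic covariate and from -0.23 to 0.010 with a participant left out, and PYY at -0.063 without cross-hybridising probe sets. For pre-diabetes, PRKCB was at -0.041 with the mean of probe sets and S100A9 at 0.028 without the 3 arrays, also among abundant genes. List medians for IR turned for oxidative phosphorylation without a filter (0.0073), with the GAPDH (0.013) and the glycaemic covariate (0.034). With the latter erythroid (-0.013), liver (-0.00081), ribosomal (0.016) and endoplasmic reticulum stress lists (0.013) turned too. Without the 3 arrays B cell (0.012), oral epithelium (-0.038) and adipokine lists (-0.0093) turned. For pre-diabetes, liver (0.013) and fatty acid lists (0.0040) turned without a filter and the latter with the GAPDH covariate (0.014). Without the 3 arrays insulin (0.0011), NF-kB (0.12), oxidative phosphorylation (0.066), ribosomal (0.27) and immediate early lists (0.12) turned.

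The replicate number as a block gave 0 calls for IR in all participants (limma, 614 genes at an unadjusted p under 0.05, against 571 on the same 30 arrays unblocked). The 15 shared numbers did not pair arrays, with correlations of -0.39 to 0.35, 6 of 15 over 0.1, and no array closest to its own number. Signal over background limits all of this, since 3.82% of the tested genes were abundant.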

Other observations

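All tests in this part except the counts of splits were chosen after the results were seen. List scores within pre-diabetes were higher in IR high for several lists, in a contrast where 89.9% of the abundant genes were higher. The neutrophil score was 0.18 ± 0.78 (SD, n = 15) in IR high and -1.19 ± 1.01 (SD, n = 4) in IR low, a difference of 1.36 (exact permutation p = 0.00877, adjusted p = 0.0265 over 20 lists). The NF-kB and cytokine score was 0.18 ± 0.65 (SD, n = 15) against -0.98 ± 0.66 (SD, n = 4), with an exact permutation p of 0.00464 (adjusted p = 0.0265). Immediate early and heat shock genes (0.99), antimicrobial proteins (0.86), monocyte and macrophage markers (0.81) and glycolysis (0.63) had the same adjusted p in exact permutation tests, and the recalled list (1.21) had one of 0.0155. Oral epithelium (0.74, exact permutation p = 0.0501) and ribosomal proteins (0.67, exact permutation p = 0.356) were higher too without passing, while the salivary gland score differed by -0.03 (exact permutation p = 0.947). Camera with an estimated correlation passed no list here (lowest adjusted p 0.0555, and 0.0816 for neutrophil markers), while fry passed neutrophil markers and immediate early genes (adjusted p = 0.0266) and the NF-kB, glycolysis, antimicrobial and recalled lists (adjusted p = 0.0148). Without the 3 arrays of low ACTB signal 2 IR-low arrays remained, where the smallest possible exact p is 0.00833, or 0.167 adjusted for a single list among 20, so that no single list could pass. The differences were then 0.70 for neutrophil markers (exact permutation p = 0.108), 1.02 for the recalled list (exact permutation p = 0.025), 0.37 for oral epithelium (exact permutation p = 0.450) and -0.67 for ribosomal proteins (exact permutation p = 0.367). Salivary gland markers then differed by -0.72 (exact permutation p = 0.142). NF-kB (0.73), immediate early (0.59), monocyte (0.45), glycolysis (0.45) and antimicrobial lists (0.43) had smaller differences than on all arrays. Among the healthy the neutrophil scores were 0.15 ± 0.86 (SD, n = 8) in IR high and 0.08 ± 0.92 (SD, n = 11) in IR low, a difference of 0.07 (exact permutation p = 0.869). The interaction had adjusted p = 0.120 for neutrophils and 0.0898 for NF-kB in permutation tests, so the IR difference was not shown to differ between glycaemic states.

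Ribosomal scores varied together with salivary gland and oral epithelium scores over the 38 arrays, and the other relations had an r of 0.283 or less without the 3 arrays of low ACTB signal. The overall signal of each array was not controlled for, so these relations do not show a shared cell source. Over 6 relations between 4 list scores with no shared genes, ribosomal proteins followed salivary gland markers most closely, with Pearson's r = 0.805 and Spearman's rho = 0.822 (permutation p = 1e-05 for both, the smallest that 100000 permutations can give, adjusted p = 6e-05). Without the 2 farthest arrays r was 0.793, without the 3 arrays of low ACTB signal 0.772, and within IR high and IR low it was 0.791 and 0.860. Oral epithelium and ribosomal scores had r = 0.637 and rho = 0.592 (permutation p = 4e-05 and 0.00013, adjusted 0.00012 and 0.00039), and r = 0.647 without the 2 farthest arrays and 0.554 without the 3. Neutrophil scores had r = 0.533 and rho = 0.413 with ribosomal ones (permutation p = 0.00058 and 0.0107), and r fell to 0.296 without the 2 farthest arrays and to 0.209 without the 3, so that relation rests on them. With salivary gland scores the neutrophil r was 0.394 and rho 0.371 (permutation p = 0.0143 and 0.0221), and r was 0.236 without the 2 farthest arrays and 0.180 without the 3. Oral epithelium and salivary gland scores had r = 0.399 and rho = 0.358 (permutation p = 0.0127 and 0.0271), and r = 0.437 without the 2 farthest arrays and 0.283 without the 3. Neutrophil and oral epithelium scores had r = 0.141 and rho = 0.0283 (permutation p = 0.402 and 0.867), and r = -0.174 without the 3.

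Several of the brightest probe sets stayed bright on every array. TMEFF2 had a median signal of 11459 and a range of 6427 to 14305, RPS6 a median of 6192 and a lowest value of 3581, KLF3-AS1 a median of 4844 and a lowest value of 1650, and FOLR1 3101 and 794. Over the same arrays the ribosomal gene RPL41 fell as low as 63.9, S100A8 as low as 46.6 and the gene-level probe set of ACTB as low as 71.2. These genes were singled out after their values were seen, and no explanation was tested.

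The counts of genes at an unadjusted p under 0.05 were set against 100 splits of the arrays into groups of the same sizes. For IR in all participants 53 splits gave as many as the real 603, the highest other being 1744. For IR among the healthy it was 96 splits (real 327, highest other 1625), for pre-diabetes adjusted for IR 48 (624 and 1525), for pre-diabetes within IR high 38 (646 and 1612) and for the interaction 12 (958 and 1635). The 7 lists called for pre-diabetes were matched by 16 splits, the highest other being 11 lists. Chance could not be excluded for any of these counts, and splits with 1525 to 1744 genes may reflect a structure of the arrays or correlation between genes, which was not tested.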
